A study of Arabidopsis thaliana with 12 samples.

How the data were processed

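RNA was measured by stranded, poly(A)-selected RNA sequencing in 12 Arabidopsis thaliana samples of the Landsberg erecta background, 3 libraries in each of 4 groups. Per the labels, the groups were rosette leaves of flowering wild-type plants, apices of the ap1 cal 35S::AP1-GR line before treatment (day 0), apices of the same line 2 days after 10 µM dexamethasone (day 2), and wild-type main inflorescences without their oldest flowers. In the 35S::AP1-GR line the floral regulator APETALA1 is fused to the hormone-binding part of the glucocorticoid receptor, which keeps it inactive until dexamethasone is given. The ap1 cal double mutant makes masses of inflorescence-like meristems in place of flowers until then.

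The values used were FPKM (fragments counted relative to transcript length and to the mapped fragments of the library) deposited by the authors in a table with a single value per gene and group, so the 3 libraries of a group had already been merged. The unit was inferred from the values and from the presence of Cufflinks in the submitters' processing notes, because the table's header names only the genes and the groups. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie2 2.1.0, TopHat2 2.0.10 and Cufflinks 2.1.1, with genome build TAIR10. The gene annotation, the options, the way the libraries were merged and any scaling between groups are not given in the sources used here. Because short reads from near-identical gene copies can be divided between them in such a pipeline, values of single members of the RBCS, LHCB1 and histone families are uncertain.

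The table held 34133 rows and 33559 different gene identifiers. The rows of the 567 identifiers that occurred more than once were summed, since a Cufflinks gene value is the sum of its parts; 11 of these 1141 rows reached 5 FPKM in any group. Symbols and gene classes were taken from the RefSeq annotation of assembly TAIR10.1, in which 32815 identifiers were found, and transcript lengths from the same annotation. Since the authors' build carries another name, no coordinates from it are given, and the lengths are approximate.

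No per-library values were used, so no test, standard deviation or p-value could be computed, and the spread between libraries is unknown. The design fixed before the data were examined foresaw a replicate-based test for per-library values and, for a table of merged groups, a rule of size, which was used here. Genes with at least 1 FPKM in at least 1 group were kept (22289). The difference between 2 groups was taken as log2 of (FPKM + 1) in the first minus log2 of (FPKM + 1) in the other, which understates the difference of genes with low values. A gene was called higher or lower when this difference was at least 1 (2-fold on that scale) and its value in the higher group was at least 5 FPKM. Ratios given as "fold" are ratios of the FPKM values themselves, and no ratio is given against a group listed at 0.

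The 4 comparisons, 22 gene lists and the rule for named genes were also fixed beforehand. The lists covered floral meristem and organ identity, floral organ development, flowering time and inflorescence identity, shoot meristem and boundary, organ primordium and polarity, photosynthesis, DNA replication, mitosis, replicative histones, anther with tapetum and pollen wall, meiosis, auxin, gibberellin, cytokinin, Polycomb and Trithorax group, flavonoid, heat shock, touch and wounding, defence and senescence, secondary wall and xylem, stomata and trichomes, and reference genes. From the Polycomb list, 1 member was dropped because the reference gave its identifier another name. The median log2 difference of each list was placed among the medians of 10000 random lists of the same size. These were drawn from 20 bins of mean expression over all 4 groups. A list stood apart when its median lay outside the central 95% of the random medians. About 1.1 of the 22 lists would do so by chance in a comparison if the genes of a list were independent. Genes of a pathway are not, so the percentile describes these values and is not a p-value.

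Named genes were AP1, CAL and the rest of the floral identity list; the 10 highest and 10 lowest log2 differences of each comparison, of which genes without a symbol could be left out after the first 3; up to 2 members per direction of every other list; and each flowering-time gene past the rule. The first 4 members of a list could also be named without passing. Genes named outside this rule were chosen after their values were seen, and they are marked where they stand.

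The rule was tested on simulated values in which 200 genes were changed by a known fold under a noise of 0.2 on the log2 scale. For day 2 against day 0 (18226 genes) it recovered 85.0% of the genes changed 2.5-fold and 99.5% of those changed 4-fold, with 5 and 7 unchanged genes called. For inflorescences against day 2 (18061 genes) it recovered 82.0% and 100%. With the leaf values as the base (18888 genes) it recovered 81.0% and 100% for day 0, and 86.5% and 100% for inflorescences. The noise of 0.2 was assumed, because the spread between libraries is unknown. Only genes with at least 1 FPKM in the base group were simulated, and the changed genes were drawn from those with at least 10 FPKM there. Recovery of genes with lower values was therefore not measured. In the data, 20 genes called higher at day 2 were listed at 0 at day 0. The recovery and the false calls therefore describe the simulation and are not error rates of the calls reported below.

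Depth was estimated from the lowest values. In genes with a single annotated transcript longer than 1000 nt, FPKM multiplied by the transcript length in kb less 200 nt piled up at distinct levels, as it would if a level were a single read. The fullest level was 0.0123 in leaves, with a smaller one at 0.00848, and 0.00673, 0.00806 and 0.00833 in day-0 apices, day-2 apices and inflorescences. A value of 5 FPKM in a transcript of 1 kb effective length then corresponds to about 407 such steps in leaves and to 743, 620 and 600 in the other groups, so counting error would be small beside a 2-fold difference except in very short genes. The ratio of the leaf levels, 1.45, is not a whole number, so the step in leaves is uncertain. Only levels from 0.005 to 0.03 were searched, and the 200 nt were those that gave the largest pile-up. Alternatives tried were other pseudocounts, filters and thresholds, 3 rescalings of the groups, and gene sets without 0 values or repeated identifiers. Analyses that need per-library values were not run. Some genes that the naming rule allows are not reported here. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.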

Results

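The expression table described 4 stages and tissues around early flower development: rosette leaves, apices of ap1 cal 35S::AP1-GR plants at day 0 and at day 2 after dexamethasone, and wild-type inflorescences. The 3 libraries of each group had been merged, so there are no replicate values and none of the differences below has a replicate check. At least 1 FPKM was reached by 18888 genes in leaves, 18226 at day 0, 18061 at day 2 and 21018 in inflorescences. FPKM summed to 1283890 in leaves, 900514 at day 0, 873400 at day 2 and 925754 in inflorescences, and the 10 most abundant genes held 7.49%, 5.78%, 5.08% and 4.85% of these sums. Of the reference genes, PP2AA3 stood at 40.6, 40.3, 39.9 and 38.2 FPKM and SAND at 32.5, 31.5, 31.8 and 32.3 FPKM in leaves, day-0 apices, day-2 apices and inflorescences, whereas ACT2 was 5.32-fold higher in leaves than at day 0.

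AP1 itself (AT1G69120) stood at 659 FPKM at day 0 and 813 FPKM at day 2, against 0.429 FPKM in leaves and 151 FPKM in inflorescences. These values do not separate the transgene's transcript from that of the mutated gene. Its close relative CAL (AT1G26310) was listed at 0 in leaves and stood at 16.8, 14.6 and 8.21 FPKM at day 0, at day 2 and in inflorescences. Neither gene met the rule between day 0 and day 2.

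The comparison of day 2 with day 0 asks what differs in these apices 2 days after AP1-GR was activated. No mock-treated samples are labelled, so treatment and elapsed time cannot be separated. Several floral organ identity genes were higher at day 2. AP3 (AT3G54340), which specifies petals and stamens, was 154-fold higher, at 202 FPKM at day 2 against 1.31 FPKM at day 0. Its partner PI (AT5G20240) was 5.34-fold higher at 107 FPKM, AG (AT4G18960), needed for stamens and carpels, was 19.9-fold higher at 16.9 FPKM, and the cofactor SEP3 (AT1G24260) was 15.7-fold higher at 65.2 FPKM. On the lower side stood TFL1 (AT5G03840), which maintains the inflorescence meristem and was 6.02-fold lower at 13.7 FPKM, and LSH1 (AT5G28490), a gene of the ALOG family named after its values were seen, at 7.58 FPKM against 123 FPKM.

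By the rule of size, 182 genes were higher and 366 lower at day 2, which is 2.46% of the 22289 genes compared. Of all genes, 88.8% differed by no more than 0.5 on the log2 scale. Both shares include genes low in both groups of apices, which cannot be called and whose differences the pseudocount holds towards 0. Of the 14992 genes of 500 nt or more with at least 5 FPKM in either group, 3.16% met the rule. Of the 16 floral meristem and organ identity genes, 9 were higher and none lower, and the list's median difference of 1.32 lay at the 100th percentile of random lists. Besides AP3, PI, AG and SEP3, they were SEP1 at 13.6 against 4.02 FPKM, SEP2 at 83.2 against 38.3 FPKM, AP2 at 63.2 against 19.4 FPKM, the meristem identity gene LFY (AT5G61850) at 158 against 45.2 FPKM and its coregulator UFO (AT1G30950) at 64.1 against 19.4 FPKM. FUL at 127 against 193 FPKM, SEP4 at 45.5 against 32.6 FPKM, LMI1 at 7.04 against 8.46 FPKM, AGL6 at 38.6 against 25.8 FPKM and PAN at 79.5 against 50.8 FPKM did not meet it.

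**Figure D1:**
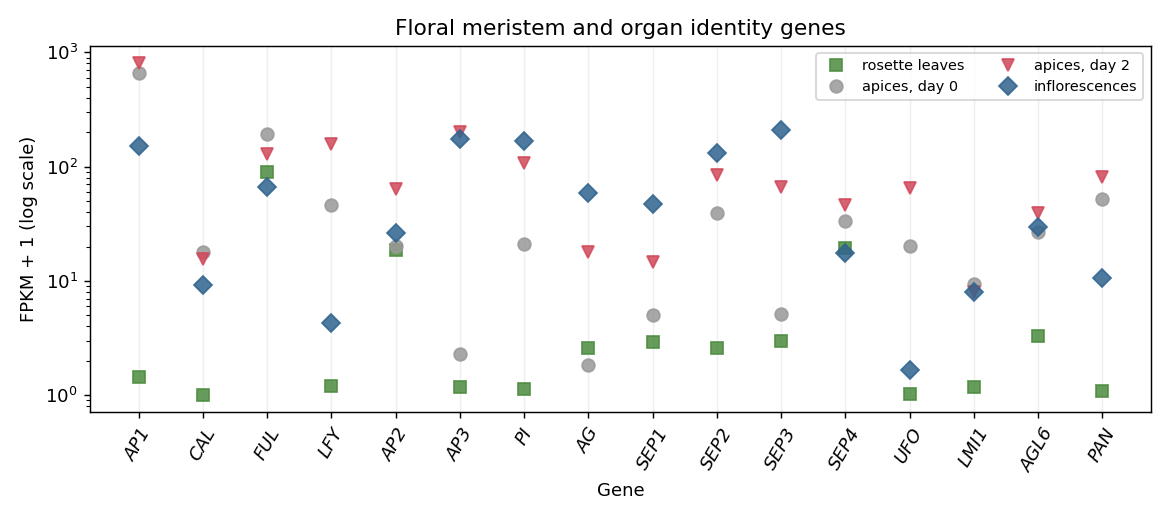
FPKM + 1 on a log axis for the 16 floral meristem and organ identity genes, 1 point per group, each the authors' merged value of 3 libraries with no error available. AP3 stands at 202 FPKM at day 2 against 1.31 FPKM at day 0, and LFY and UFO are highest at day 2 among the 4 groups.

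Of 23 measured flowering-time and inflorescence identity genes, 6 were lower at day 2 and none higher, with a median difference of -0.58 below all random lists. They were TFL1, FD at 65.7 against 159.9 FPKM and its paralog FDP at 36.4 against 86.0 FPKM, SPL9 at 33.3 against 72.9 FPKM, SPL15 at 5.56 against 16.2 FPKM and TOE3 at 1.95 against 5.46 FPKM. FD and FDP encode bZIP proteins, and the SPL genes promote the floral transition. AGL24 at 66.1 against 118 FPKM, SVP at 41.3 against 81.9 FPKM and SOC1 at 135 against 203 FPKM were lower without meeting the rule.

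In the organ primordium and polarity list (median 0.38), DRNL, which marks organ founder cells, stood at 39.3 against 12.6 FPKM and HB8 at 24.6 against 11.5 FPKM, while YAB2 was lower at 3.00 against 7.11 FPKM. In the floral organ development list (median 0.11), NUB at 11.5 against 0.963 FPKM and JAG at 6.57 against 0.243 FPKM were higher, both regulators of lateral organ growth, and the other 16 members met no rule. Of 21 shoot meristem and boundary genes, 18 met no rule, among them STM at 217 against 195 FPKM, and the median of -0.02 lay inside the random range. The boundary gene CUC1 was higher at 62.6 against 19.7 FPKM, and the ALOG genes LSH4 at 12.8 against 72.4 FPKM and LSH3 at 54.5 against 149.6 FPKM were lower. None of the 13 DNA replication genes, 25 mitosis genes or 13 replicative histone genes met the rule, although the list medians of 0.14, 0.21 and 0.42 lay at the 99.3rd, 100th and 100th percentiles.

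Hormone genes differed in both directions. The gibberellin synthesis gene GA3OX1 was 36.1-fold higher than its 0.504 FPKM at day 0 and the DELLA gene RGL2 stood at 12.5 against 2.97 FPKM, whereas GA20OX1, an earlier step of the synthesis, was 4.11-fold lower at 1.96 FPKM. That list's median of 0.08 lay inside the random range. In the auxin list (median 0.39, 100th percentile), IAA14 at 5.28 against 1.76 FPKM and IAA1 at 14.0 against 6.36 FPKM were higher and the auxin-conjugating enzyme gene GH3.6 was lower at 7.19 against 25.5 FPKM. Of 16 cytokinin genes, the response regulators ARR7 at 42.5 against 94.3 FPKM and ARR15 at 5.06 against 11.5 FPKM were lower, with a list median of -0.35 at the 0.01th percentile.

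Several stress-related and pigment genes were lower at day 2. In the touch and wounding list 5 of 16 genes were lower and none higher (median -0.60, below all random lists), led by the jasmonate repressor JAZ8, 4.56-fold lower than its 11.4 FPKM at day 0, and WRKY33 at 19.7 against 56.5 FPKM. WRKY70 was lower at 78.9 against 196 FPKM, while the median of its defence and senescence list was 0.18, at the 99.3rd percentile. The late anthocyanin genes LDOX and DFR stood at 0.522 against 8.19 FPKM and 0.536 against 7.35 FPKM, although the flavonoid list as a whole had a median of 0.29, at the 99.98th percentile. The means of the flavonoid and defence lists were negative, at -0.26 and -0.08. Of 49 photosynthesis genes, 2 met the rule, LHCB1.1 at 22.2 against 53.3 FPKM and PSBO2 at 38.8 against 81.0 FPKM. The list's median was -0.29, below all random lists. The value of LHCB1.1 is uncertain because near-identical copies share reads. The trichome gene GL2 was lower at 1.70 against 6.07 FPKM, in a stomata and trichomes list with a median of -0.07. The anther, tapetum and pollen wall list had no gene past the rule and a median of 0.08 at the 98.6th percentile. Its members include genes near 0 in both groups of apices, such as ATA7 at 0.252 FPKM at day 0 and 0.262 FPKM at day 2. Matching on all 4 groups could pair these with genes of other levels in the apices. The list also stood apart against unmatched random lists, but those are not matched on level at all and cannot settle this. The meiosis, Polycomb and Trithorax, heat shock, secondary wall and reference lists had no gene past the rule either, and their medians of -0.01, -0.01, -0.03, -0.17 and 0.05 lay inside the random range. In all, 14 of the 22 lists stood apart in this comparison.

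The largest log2 differences of this comparison were largely genes listed at 0 in either group. CAT3, a catalase gene, was listed at 0 in every group except day 2, where it stood at 335 FPKM. AT4G32330 and AT1G15280 were listed at 0 at day 0 only and stood at 60.2 and 34.4 FPKM at day 2, and the microRNA locus MIR166d and the small nucleolar RNA gene AT4G26365 stood at 32.1 and 27.8 FPKM at day 2 and were listed at 0 at day 0. AT1G28730, AT2G43137 and AT2G43139, at 39.8, 35.6 and 27.0 FPKM at day 0, were listed at 0 at day 2. Among nuclear protein-coding genes above 0 in both groups, a restriction chosen after these values were seen, 151 were higher and 316 lower. In that ranking AP3 came first, followed among genes with a symbol by SEP3, GA3OX1, AG and the sugar transporter gene SWEET1 at 64.5 against 6.61 FPKM. On the lower side LSH1 was followed by MIOX4 at 0.203 against 11.7 FPKM, FAF3 at 7.05 against 51.4 FPKM, BT5 at 4.11 against 31.7 FPKM, LDOX, TFL1 and LBD39 at 7.85 against 49.1 FPKM.

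Inflorescences, with flowers up to a late stage before opening, were next compared with day-2 apices. Genotype, stage, treatment and the sampled tissue differ together in this comparison. The values do not separate lower expression of a gene from a smaller share of the tissue that expresses it. Genes of pollen and tapetum had the highest differences among genes with a symbol. GRP19, a glycine-rich pollen coat protein gene, stood at 2260.2 FPKM in inflorescences and 0.0196 FPKM at day 2, LTP12, a tapetal lipid transfer protein gene, at 1138 against 0.0218 FPKM, and AT1G66850 of the lipid transfer and seed storage protein family at 2009.9 against 0.108 FPKM. Several early floral regulators were lower. UFO was 95.4-fold lower at 0.673 FPKM, LFY 47.8-fold lower at 3.31 FPKM, and DRNL 192-fold lower at 0.205 FPKM.

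In this comparison 3100 genes were higher and 940 lower in inflorescences, and 363 of these calls involved a group listed at 0. Of the 22 anther, tapetum and pollen wall genes 19 were higher and none lower, with a median of 4.60 at the 100th percentile. GRP17 was listed at 0 at day 2 and stood at 738 FPKM, and ATA7 stood at 316 against 0.262 FPKM. Other top genes with a symbol on this side were ATA27 at 581 FPKM, GRP20 at 490.1 FPKM (listed at 0 at day 2), AGP23 at 538 FPKM and EXL4 at 449.5 FPKM, and those without a symbol were AT4G04078 at 744 FPKM and AT1G68875 at 520.1 FPKM, both listed at 0 at day 2. The lower side began with CAT3, at 335 FPKM at day 2, and AT3G25719, at 168 FPKM, both listed at 0 in inflorescences, followed by the small nucleolar RNA gene AT2G35742, at 64.7 FPKM and then 0, and the pseudogene AT4G00413 at 1.76 against 146 FPKM. Values of short RNA genes such as AT2G35742 are uncertain in poly(A)-selected libraries. Further down, AHP6 (listed in the reference as HP6), an inhibitor of cytokinin signalling, stood at 1.26 against 84.7 FPKM, and the MADS-box gene AGL71 at 1.35 against 79.2 FPKM.

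The floral identity list split, with 3 genes higher, 6 lower and a median of -0.59 at the 0.02th percentile. AG at 58.3 against 16.9 FPKM, SEP1 at 46.6 against 13.6 FPKM and SEP3 at 207 against 65.2 FPKM were higher. Lower were LFY, UFO, AP1 at 151 against 813 FPKM, AP2, 2.52-fold lower than its 63.2 FPKM at day 2, SEP4 at 16.5 against 45.5 FPKM and PAN at 9.65 against 79.5 FPKM. The AP1 value at day 2 may include the transgene's transcript, so its call cannot be read as a difference of stage. AP3 at 173 against 202 FPKM, PI at 166 against 107 FPKM and SEP2 at 129.6 against 83.2 FPKM met no rule, and neither did FUL, CAL, LMI1 or AGL6. Of the 18 floral organ development genes 8 were higher and 4 lower (median 1.70, 99.5th percentile), with the ovule gene STK at 32.9 against 0.433 FPKM and the carpel gene SHP1 at 27.5 against 0.975 FPKM. NUB at 2.07 against 11.5 FPKM and ETT (also ARF3) at 45.9 against 183 FPKM were lower. That list stood inside the random range with a pseudocount of 0.1.

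Of 21 shoot meristem and boundary genes 16 were lower and none higher (median -2.08), with CUC1 at 4.98 against 62.6 FPKM and the stem cell signal gene CLV3 at 0.0768 against 9.14 FPKM. Of 19 organ primordium and polarity genes 10 were lower, including AIL6 at 6.10 against 55.9 FPKM, and YAB2 at 16.9 against 3.00 FPKM and AS2 at 19.0 against 4.41 FPKM were higher (median -1.07). In the DNA replication list 3 of 13 genes were lower, among them PCNA1 at 38.6 against 98.6 FPKM, and in the mitosis list 10 of 25, among them PLE at 18.9 against 44.2 FPKM. The replicative histone list had 12 of 13 genes lower, and the medians of these 3 lists, -0.86, -0.95 and -1.44, lay below all random lists. The exception, AT5G10400, is a copy of the histone H3.1 genes and was 5.01-fold higher in inflorescences. Its value is uncertain because near-identical copies share reads.

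All 49 photosynthesis genes were higher in inflorescences than at day 2, with a median of 1.90 and LHCB1.1 at 507 against 22.2 FPKM. The value of LHCB1.1 is uncertain because near-identical copies share reads. The secondary wall list had all 8 measured genes higher (median 2.28), with LAC4 25.9-fold higher at 33.7 FPKM and NST1 at 6.86 against 0.159 FPKM. Of the flowering-time genes FLC at 7.31 against 0.133 FPKM, TOE3 at 13.0 against 1.95 FPKM and SPL15 at 17.5 against 5.56 FPKM were higher, and FD at 3.28 against 65.7 FPKM, SVP at 4.29 against 41.3 FPKM, FDP at 4.18 against 36.4 FPKM, AGL24 at 11.1 against 66.1 FPKM, TFL1 at 2.65 against 13.7 FPKM and SOC1 at 37.2 against 135 FPKM were lower, with a median of -0.19 inside the random range. The touch and wounding list stood apart (median 0.55, 99.4th percentile), with LOX2 at 347 against 39.2 FPKM, but inside the range against random lists not matched on expression. Of the Polycomb and Trithorax genes 1 of 24 was higher, ULT2 at 14.6 against 0.165 FPKM, and the median of -0.31 lay at the 1.53rd percentile. The meiosis, auxin, gibberellin, cytokinin, flavonoid, heat shock, defence, stomata and reference lists lay inside the random range, with medians of 0.09, 0.40, -0.23, 0.56, 0.39, -0.12, 0.96, 1.24 and -0.06. Within them RGL2 was higher at 48.4 against 12.5 FPKM and the cytokinin response regulator gene ARR16 was higher at 34.6 against 1.82 FPKM.

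Day-0 apices and rosette leaves differ in tissue and genotype together, and this comparison shows the meristem-rich state from which flower formation was induced. Meristem and cell division genes were far higher in the apices, and leaf photosynthesis and defence genes far lower. STM, needed to keep the shoot meristem, stood at 195 FPKM against 0.159 FPKM in leaves, KNAT1 at 103 against 0.236 FPKM, and the cytokinesis gene KN at 153 against 3.63 FPKM. The pathogenesis-related genes PR2 (listed in the reference as BGL2) and PR5 stood at 1.33 and 1.87 FPKM against 1726 and 872 FPKM in leaves.

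By the rule of size 3622 genes were higher and 5116 lower in apices, so 41.5% of the calls were on the higher side. After rescaling to the upper quartile this split turned to 4721 higher and 4034 lower, or 53.9%, since that rescaling shifted the median of all genes by 0.15. Of the 21 shoot meristem and boundary genes 19 were higher and none lower (median 3.78). Of 25 mitosis genes 24 were higher (median 4.03), as were 10 of 13 DNA replication genes (median 2.90), led by PCNA1 at 84.6 against 5.15 FPKM, 12 of 13 replicative histone genes (median 3.22) and 13 of 19 organ primordium and polarity genes (median 2.05), led by ANT at 110.5 against 2.24 FPKM. Each of these 5 medians lay above all random lists. The organ polarity gene YAB5 was lower at 6.86 against 30.5 FPKM.

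Of the floral identity genes 10 were already higher at day 0 than in leaves and none lower (median 3.02): AP1, CAL, FUL at 193 against 88.6 FPKM, LFY, PI, 163-fold higher, SEP2 at 38.3 against 1.59 FPKM, UFO at 19.4 against 0.0222 FPKM, LMI1 at 8.46 against 0.177 FPKM, AGL6 at 25.8 against 2.29 FPKM and PAN at 50.8 against 0.0952 FPKM. The AP1 value at day 0 may include the transgene's transcript, so its call cannot be read as a difference of tissue. CAL is mutated in this line too, so its value at day 0 is that of the mutated gene. AP3, AG, SEP1, SEP3, AP2 and SEP4 met no rule. Flowering-time genes went both ways, with 10 higher and 7 lower and a median of 0.14 inside the random range. FDP at 86.0 against 0.383 FPKM, TFL1 at 82.4 against 2.31 FPKM, FD at 159.9 against 7.52 FPKM, SPL15 at 16.2 against 0.431 FPKM, SPL9 at 72.9 against 5.89 FPKM, AGL24 at 118 against 13.8 FPKM, SPL5 at 73.5 against 8.50 FPKM, SPL4 at 321 against 78.0 FPKM, SPL3 at 28.0 against 6.94 FPKM and AGL42 at 73.8 against 22.1 FPKM were higher. The repressor TEM2 at 0.512 against 125 FPKM, the florigen gene FT at 0.713 against 41.1 FPKM, its homolog TSF at 0.0571 against 12.8 FPKM, SNZ at 0.360 against 20.9 FPKM, AGL19 at 0.964 against 9.56 FPKM, TOE1 at 6.68 against 41.5 FPKM and TEM1 at 26.6 against 145 FPKM were lower.

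The photosynthesis list had 47 of 49 genes lower in the apices (median -3.03, below all random lists). Among them was LHCB1.1 at 53.3 against 1525 FPKM, a value that is uncertain because near-identical copies share reads. The other 2 of the 49, RBCS1A and LHCB1.3 (CAB1 in the reference), were listed at 0 in leaves and stood at 2493 and 1556 FPKM at day 0. Of 9 defence and senescence genes 7 were lower (median -6.02, below all random lists), and of 16 touch and wounding genes 10 were lower (median -1.57, 0.1th percentile), with the jasmonate synthesis gene LOX2 at 26.4 against 1045 FPKM. The storage protein genes VSP1 at 1010.2 against 72.1 FPKM and VSP2 at 1143 against 136 FPKM were higher in that same list. Also apart on the higher side stood floral organ development (median 0.42, 98.7th percentile), which lay inside the range after rescaling to the upper quartile or against unmatched random lists, meiosis (median 1.09) with DMC1 at 6.40 against 0.929 FPKM, and Polycomb and Trithorax (median 0.61) with 7 of 24 genes higher, led by ULT1 at 41.2 against 2.37 FPKM. The anther, auxin, gibberellin, cytokinin, flavonoid, heat shock, secondary wall, stomata and reference lists lay inside the random range, with medians of 0.17, 0.00, 0.14, -0.48, -0.65, -0.63, -0.42, 0.36 and -0.12.

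Among the largest differences with a symbol, LTP6 stood at 3966 FPKM at day 0 against 7.14 FPKM in leaves, PDF1, an epidermal gene of the shoot tip, at 1315 against 3.24 FPKM, FTM1, a fatty acid desaturase gene, at 317 against 0.0647 FPKM and CYP706A3 at 333 against 0.171 FPKM. Without a symbol, the tRNA genes AT1G15090 and AT1G28820 stood at 756 and 319.7 FPKM and were listed at 0 in leaves, and AT1G62500 stood at 454 against 0.342 FPKM. Both tRNA values are uncertain, since the libraries were poly(A)-selected and counting error can be large in very short genes. The genes lower at day 0 included ECS1 at 0.821 against 2848 FPKM, PCR1 at 1.13 against 1418 FPKM, LHB1B1 at 3.55 against 2789 FPKM and GSTF7 at 0.399 against 611 FPKM. The first 3 without a symbol on that side were AT1G23130, AT2G25510 and AT1G64360, at 4287, 4186 and 992 FPKM in leaves.

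**Figure D2:**
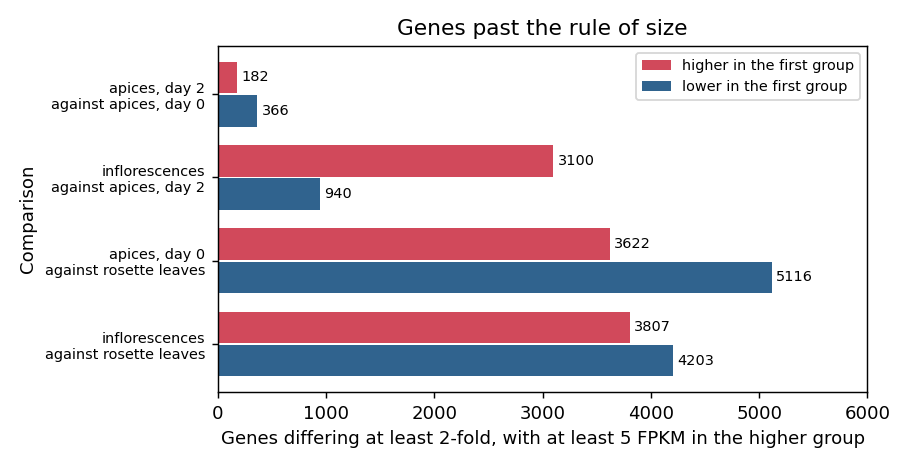
Number of genes (x axis, from 0) that differed at least 2-fold with at least 5 FPKM in the higher group, as higher and lower bars for the 4 comparisons. Day 2 against day 0 has 182 and 366 genes, and the comparisons with leaves have between 3622 and 5116 genes per direction.

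The wild-type inflorescences and leaves share a genotype, and this comparison shows how wild-type flower-bearing tissue and leaf tissue differ. Floral organ genes and anther genes stood out in inflorescences: AP3 at 173 against 0.170 FPKM, PI at 166 against 0.123 FPKM, the carpel gene CRC at 48.6 against 0.0167 FPKM and the tapetum gene A9 at 504 against 0.377 FPKM. In leaves, PR2 at 1726 against 2.01 FPKM, PR1 at 249 against 0.913 FPKM and the phospholipase gene PLA2A at 448 against 2.55 FPKM were higher, as were AT1G64360, AT1G30250 and AT5G52740, at 992, 1065 and 259 FPKM, GSTF7 at 611 against 1.54 FPKM and PCR1 at 1418 against 5.32 FPKM. AT2G20870, annotated as a cell wall protein, stood at 2241 FPKM in inflorescences against 0.698 FPKM in leaves, and GRP19, AT1G66850, LTP12, AT4G04078, GRP17 and ATA27 were among the 10 highest here too. Of all genes, 3807 were higher and 4203 lower in inflorescences, so 47.5% of the calls were on the higher side. This share was 60.4%, with 4784 higher and 3143 lower, after rescaling to the upper quartile, which shifted the median of all genes by 0.29.

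Of the floral identity genes 11 were higher and none lower (median 3.24). Besides AP3 and PI they were AP1, CAL, AG at 58.3 against 1.59 FPKM, SEP1 at 46.6 against 1.90 FPKM, SEP2 at 129.6 against 1.59 FPKM, SEP3 at 207 against 1.99 FPKM, LMI1, AGL6 and PAN, and the early genes LFY and UFO met no rule, at 3.31 and 0.673 FPKM in inflorescences. The lists of floral organ development (10 of 18 higher, median 2.16), anther, tapetum and pollen wall (20 of 22, median 5.30), shoot meristem and boundary (11 of 21, with 1 lower, median 1.56), organ primordium and polarity (9 of 19, with 1 lower, median 1.12), DNA replication (10 of 13, median 2.13), mitosis (24 of 25, median 3.31), replicative histones (12 of 13, 100th percentile), auxin (9 of 24 higher and 7 lower, median 0.73) and secondary wall (6 of 8, median 1.88) stood apart on the higher side. The anther gene TPD1 was an exception and was lower, at 9.61 against 40.1 FPKM. The auxin list lay inside the random range when no filter on low values was used.

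On the lower side stood photosynthesis (42 of 49 lower, median -1.61), with PSBR at 1373 against 7287 FPKM, defence and senescence (7 of 9 lower, median -4.15), touch and wounding (9 of 16 lower and 2 higher, median -1.56), with ZAT10 at 36.8 against 535 FPKM, and heat shock (3 of 5 lower, median -1.54, 2.22nd percentile), with HSP70-4 at 6.59 against 21.7 FPKM. The heat shock list lay inside the random range under 4 of the 6 alternatives. RBCS1A and LHCB1.3, listed at 0 in leaves, stood at 8661 and 4113 FPKM in inflorescences. Flowering-time genes were higher in 6 cases, SPL15 at 17.5 against 0.431 FPKM, SPL9 at 65.2 against 5.89 FPKM, FLC at 7.31 against 0.131 FPKM, SPL5 at 47.5 against 8.50 FPKM, SPL3 at 27.7 against 6.94 FPKM and TOE3 at 13.0 against 5.11 FPKM, and lower in 9, led by TEM2 at 2.96 against 125 FPKM and SNZ at 0.101 against 20.9 FPKM, with SVP at 4.29 against 85.7 FPKM, SOC1 at 37.2 against 207 FPKM, TOE1 at 1.83 against 41.5 FPKM, TEM1 at 18.7 against 145 FPKM, AGL19 at 0.349 against 9.56 FPKM, FT at 9.45 against 41.1 FPKM and TSF at 1.84 against 12.8 FPKM (median -0.27, inside the random range). The flavonoid gene FLS1 was higher at 224 against 28.4 FPKM and the anthocyanin genes DFR and LDOX were lower at 1.96 against 95.7 FPKM and 2.62 against 92.3 FPKM, in a list with a median of 0.09 inside the range. The meiosis, gibberellin, cytokinin, Polycomb and Trithorax, stomata and reference lists lay inside it as well, with medians of 1.23, 0.32, -0.52, 0.28, 0.59 and -0.29.

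**Figure D3:**
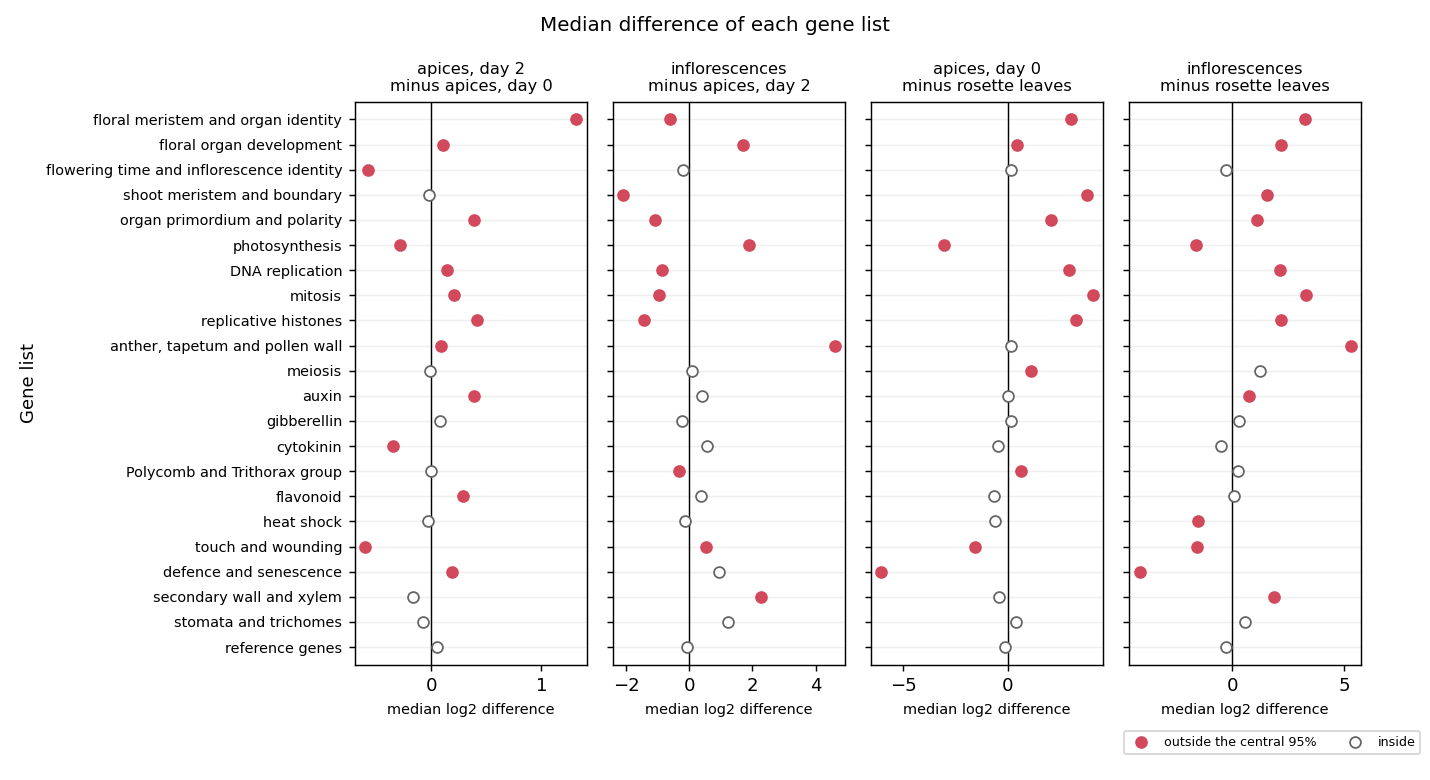
Median log2 difference (x axis, a different scale in each panel) of the 22 gene lists in the 4 comparisons, 1 point per list, filled where the median lay outside the central 95% of 10000 random lists. The floral identity list stands at 1.32 in day 2 against day 0, and the anther list at 4.60 and 5.30 in the comparisons of inflorescences with day 2 and with leaves.

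Whether the genes that differ at day 2 are those that distinguish inflorescences from leaves was asked with 2 comparisons that share no library. Across the 22289 genes the log2 differences had a Pearson r of 0.158 and a Spearman rho of 0.169, and genes are not independent replicates. Shared genes were counted against the 14785 genes that reached 5 FPKM in both comparisons, a background chosen after the values were seen. Of the genes higher at day 2, 67 were also higher in inflorescences than in leaves, where independent lists would share 24.2, and 36 were lower, where they would share 24.8. Of the genes lower at day 2, 161 were also lower in inflorescences, where independent lists would share 58.1, and 75 were higher, where they would share 56.7. All 4 counts, those of opposite direction included, exceeded these numbers. Over all 22289 genes the numbers for independent lists were 31.1, 34.3, 69.0 and 62.5 in the same order.

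Genes with a value at least 4 times that of every other group, on the FPKM + 1 scale, and at least 5 FPKM were counted last. There were 1632 for leaves, 976 for inflorescences, 18 for day 0 and 12 for day 2. Of these, 13 of day 0 and 8 of day 2 were listed at 0 in every other group, and 8 and 5 were nuclear protein-coding genes. LSH1, TFL1, LSH4 and RTFL13 were among those of day 0, and CAT3, listed at 0 elsewhere, NUB, the purine permease gene PUP4 at 36.5 FPKM and AT5G03545, annotated as a phosphate starvation response gene, at 75.2 FPKM, were among those of day 2. RTFL13, PUP4 and AT5G03545 were named after their values were seen. Day 0 and day 2 are apices of the same line, and a gene whose values there lie within 4 times of each other can count for neither. FTM1 was left out in this way, at 317 and 125 FPKM at day 0 and day 2 against 0.0647 FPKM in leaves and 2.80 FPKM in inflorescences. The small counts for day 0 and day 2 therefore do not show that few genes prefer apices. The preference for inflorescences included 19 of the 22 anther, tapetum and pollen wall genes, and that for leaves 7 of the 9 defence and senescence genes and 7 of the 23 flowering-time genes, among them FT, TSF, TEM1 and TEM2.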

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

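The background of the shared-gene counts, the restriction to nuclear protein-coding genes above 0, the sets without repeated identifiers or without 0 values, and the list results after upper-quartile and reference-gene rescaling were chosen after the data had been seen; the other alternatives were fixed before. No paired analysis was possible because the columns carry no replicate values, and for the same reason count models, limma, leaving out replicates and an estimated correlation within lists were not run. With a threshold of 4-fold and 20 FPKM the counts became 65 (31 higher, 34 lower) for day 2 against day 0, 927 (788 and 139) for inflorescences against day 2, 3143 (1013 and 2130) for day 0 against leaves and 2376 (937 and 1439) for inflorescences against leaves, by its own construction. All other alternatives kept each of these 12 counts within 1.5 times the main count. Those on the filter change nothing, since a called gene has at least 5 FPKM. Rescaling to reference genes shifted the median of all genes by 0.13 in inflorescences against leaves and turned that split to 4218 higher and 3689 lower. The number of lists standing apart stayed at 14 for day 2 against day 0, with the same 14 lists, and ranged from 12 to 14, 11 to 13 and 12 to 15 in the other comparisons, and no list that stood apart changed sign. The correlation of 0.158 was 0.123 with a pseudocount of 0.1 and 0.167 in genes of at least 5 FPKM; the cause was not tested. Genes highest in a group by only 2 times numbered 3697 for leaves, 71 for day 0 and 59 for day 2; under the 4 times rule with at least 20 FPKM, such genes numbered 9 for day 0, 7 for day 2 and 445 for inflorescences, all by construction. By construction, no named gene past the rule changed direction with a pseudocount of 0.1 or after median-of-ratios rescaling (factors from 0.958 to 1.04). After that rescaling, PSAF and GA20OX1 (inflorescences against day 2), GAPC1 (day 0 against leaves), and IAA7, FAMA, GA20OX1 and UGT78D2 (inflorescences against leaves) no longer met it. Depth limits very short genes, and the missing spread between libraries limits all small differences.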

Other observations

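All tests in this part were chosen after the result was seen, except that on clock genes. Gene families by product name were screened without a list fixed beforehand, 215 families with at least 10 measured genes. In inflorescences against day 2, the highest medians belonged to the late embryogenesis abundant family (median difference 5.64 over 10 genes, 7 of them higher), the plant self-incompatibility protein S1 family (3.67 over 12 genes, 10 higher), the MtN3 family of sugar transporters (2.31 over 14 genes, 10 higher) and the invertase and pectin methylesterase inhibitors (2.03 over 43 genes, 19 higher). Each lay above all random lists, and the median S1 gene stood at 12.3 FPKM in inflorescences against 0.0801 FPKM in leaves. The 42 TIR-NBS-LRR genes had a median of 13.0 FPKM in leaves, 2.14 at day 2 and 3.43 in inflorescences, and 31 were lower at day 0 than in leaves. The 21 CC-NBS-LRR genes had a median difference of -2.17 in the same comparison.

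Other families had higher medians at day 0 than in leaves. The 10 members of the 60S acidic ribosomal protein family had a median of 622 FPKM at day 0 against 162 FPKM in leaves (difference 2.11, 9 higher). The 13 genes named as B3 transcription factors had 24.6 against 0.0993 FPKM (difference 2.36). Between day 0 and day 2 the family medians were small. The highest was that of 19 Dof zinc finger genes, at 0.37, of which none met the rule. The K-box and MADS-box family, which includes organ identity genes of the fixed list, had 6 of 19 genes higher and none lower (median 0.23).

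A few abundant genes were listed at 0 in some groups, such as RBCS1A and CAB1 in leaves, with 8661 and 4113 FPKM in inflorescences, and CAT3 was at 0 everywhere except day 2. Failed estimates at very abundant loci are a candidate explanation, since the other 7 RBCS and LHCB1 genes were all higher in leaves than in inflorescences, by at least 1.49 times; however, AT4G32330 and AT1G15280 were at 0 at day 0 only, with 60.2 and 34.4 FPKM at day 2, so abundance does not account for every such value. Reads assigned to the other RBCS copies would have left the family's sum high in leaves, and its leaf to inflorescence ratio was 0.564, below the lowest of the other photosynthesis genes (1.34). For LHCB1 the explanations cannot be told apart, because the ratio was 2.06 with all 5 copies and 0.771 with the 3 closest ones. No biological explanation was tested.

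Short RNA genes were among the largest differences of day 2 against day 0. Of 152 genes under 200 nt with at least 5 FPKM in either group, 34.2% met the rule, against 3.16% of 14992 genes of 500 nt or more, a ratio of 10.8. This is consistent with a read counting for many FPKM in a gene shorter than the sequenced fragments. Differences in short genes between these stages stay open, since no values per library were used.

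The photosynthesis list had a median of -0.29 at day 2 against day 0, with 2 of 49 genes past the rule. Rosette leaf tissue in the day-0 samples is argued against, as the median gene would need a leaf share of 2.22%, whereas 18 of 19 genes abundant in leaves and near absent from inflorescences allow less, with a median of 0.148%, a ratio of 15.0; many of these are defence genes, so only tissue like the sampled leaves is covered. Scaling is argued against by medians of -0.35 after rescaling to reference genes and -0.27 by median of ratios. Harvest at another time of day cannot be told apart: morning and evening clock genes were both lower at day 2 (medians -0.38 and -0.42, the latter with 8 of 9 genes lower) and differed by only 0.0376, which met the bound set in advance, but all 5 morning genes were under 5 FPKM, and without a pseudocount the gap was 0.66. The activation of AP1-GR and elapsed time stay open as untested explanations.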
